A study of Mus musculus with 18 samples.

How the data were processed

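Gene expression had been measured on Affymetrix 3' expression arrays in side population (SP) and non-SP cells of 3 mouse lung carcinoma cell lines. Per the labels, 200 ng of total RNA from each sample was turned into 10 µg of biotin-labelled cRNA with a 3' IVT kit, and the arrays were processed with Affymetrix Expression Console, for which no version, summary algorithm or normalization is stated. The deposited values are log2 signals, 1 per probe set and array, for 45101 probe sets on 18 arrays. They lay between 2.28 and 15.28, and the highest array median was 6.72, and the medians differed, so the arrays had not been brought to 1 common distribution. Arrays give signals and no counts, and their number limits the precision. The 6 groups of line and fraction held 3 arrays each. The labels number the replicates 1 to 3 without saying whether they were separate cultures, sorts or hybridizations, so the spread between them may be technical and every p-value measures the spread between these samples alone.

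The values were used as deposited. The 64 control probe sets were left out of the tests. Of the other probe sets, 34958 carried 1 gene symbol and 932 carried several and were left out, and 34754 symbols were matched to current names through their gene identifiers. Each of the 18193 genes was represented by its probe set with the highest mean over all arrays. The 40% of genes with the lowest mean were then left out, and 10916 genes were tested.

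R 4.3.3 and limma 3.58.1 (lmFit, contrasts.fit and eBayes with a trend on the mean level) were used for 1 fit of all 18 arrays with 6 group means and 12 residual degrees of freedom. The contrasts were SP minus non-SP in each line, the mean of these 3 differences, the differences between them, and the differences between lines among non-SP cells. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons, the filter, 34 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule took the 8 largest increases and 8 largest decreases past the threshold in each line (10 and 10 for the mean of the lines, and the 3 genes farthest above the other lines among non-SP cells), and the 5 genes with the smallest p where none passed. It also took up to 4 members of each list described past the threshold, or 2 members with the smallest p where none passed, and in every SP comparison Abcg2, Abcb1a, Abcb1b, Abcc1 and Myc. Another gene of that rule is not reported here. Predicted genes without an ordinary symbol were passed over. Lists with fewer than 4 members above the filter were not tested, which left 32 lists. They were tested with camera at a preset correlation between genes of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry, a rotation test of whether the genes of a list move on balance one way, were run beside it. Counts adjusted over the list alone were also made.

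Whether the replicate numbers pair the SP and non-SP arrays was decided from the values before the calls of a paired fit were seen. The deviations from the group means of same-numbered arrays correlated over genes at 0.426 to 0.953 in all 9 pairs, and the 2 arrays of a pair correlated at 0.980 to 0.997. The deviation of 8 of the 9 non-SP arrays correlated best with the SP array of its own number. In A2C12 and in cRAF_cMYC 1 and 2 this r was 0.426 to 0.901, against at most 0.265 with another number. Both arrays of betaD5 1 and of cRAF_cMYC 3 resembled the other of these lines, which gives a high r (0.867 and 0.953) by itself. For betaD5 2 the r was 0.618 against 0.567 with another number, and for betaD5 3 it was 0.601 against 0.684. The arrays of betaD5 2 and 3 were each closest to an array of another pair. The numbers were taken to pair the arrays in all lines, although these values do not settle the pairing of betaD5 2 and 3. Paired results that include these arrays rest on that assumption. A fit with line and replicate number as a block, with 6 residual degrees of freedom, is given where it changes a call. The median 95% half-width of a difference in 1 line was 0.59 (log2) without the block and 0.25 with it, and for the mean of the 3 lines 0.34 and 0.14. The fits were tested on simulated data with the gene means, pair effects and spreads of these arrays. Changes of 1 (log2) in 1 line were recovered in 10.4% of genes without the block and in 91% to 94% with it. For changes of 0.5 common to the 3 lines these shares were 9% and 88.1%. The paired fit made 9 to 11 false calls in each simulated comparison and the unpaired fit made 0.

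The ratio of 3' to 5' probe sets of the control transcripts Gapdh, Actb, Tfrc and Pcx was taken per array as a measure of RNA and cDNA length, Tfrc and Pcx being added after the data had been seen. The alternatives were quantile normalization, centring on array medians, no filter or a filter at 60%, every probe set or the mean of all probe sets of a gene, no trend, array weights, each line fitted alone, each array left out in turn and the block. Alternatives for values on a linear scale were not run, since the values were already log2. Settings chosen after the data had been seen were the block combined with quantile normalization, with no filter, with the mean 3'/5' ratio of Gapdh and Actb as a covariate or with 1 effect common to the lines, each pair left out in turn, an exact sign-flip test over the pairs, and fits without pairs whose identity or RNA quality was in doubt.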

Results

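SP cells are cells that keep little of the DNA dye Hoechst because ATP-binding cassette transporters pump it out, and non-SP cells are the remaining cells of a culture. The study asked how gene expression differs between both fractions in A2C12, betaD5 and cRAF_cMYC, lines that grew out of lung tumours of mice carrying c-Raf and c-Myc transgenes. Each line and fraction had 3 arrays, 18 in all, with array medians of up to 6.72 on the log2 scale. The 6 arrays labelled A2C12 stood apart from the rest. The pair labelled betaD5 1 resembled cRAF_cMYC arrays more than the other betaD5 arrays. Its non-SP array correlated at up to 0.982 with arrays labelled cRAF_cMYC and at up to 0.925 with betaD5 arrays of another number. The non-SP array labelled cRAF_cMYC 3 correlated at up to 0.988 with arrays labelled betaD5 and at up to 0.929 with other cRAF_cMYC arrays. The lines are therefore named as labelled throughout.

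**Figure D1:**
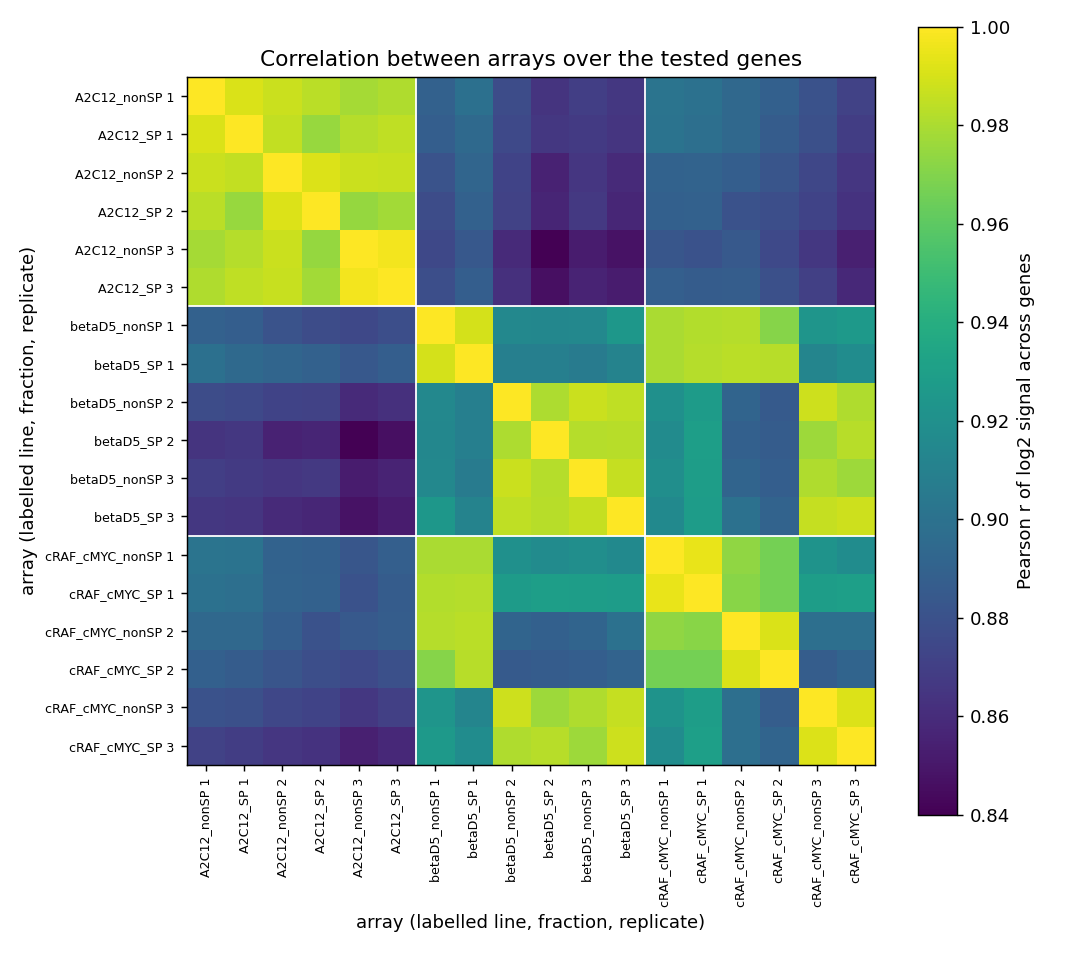
Pearson correlation over the tested genes (colour) between each pair of the 18 arrays, ordered by labelled line, replicate and fraction on both axes. The pair labelled betaD5 1 lies closer to cRAF_cMYC 1 and 2 than to betaD5 2 and 3, and the pair labelled cRAF_cMYC 3 lies closer to betaD5 2 and 3.

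In A2C12, the mitosis list, 27 genes of chromosome segregation and the G2/M phase, fell in SP cells as a group. All 27 members lay below 0, with a mean difference of -0.23 (log2; camera, adjusted p = 3.94e-23; adjusted p = 0.442 with an estimated correlation). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, went from 12.19 ± 0.23 in non-SP to 11.82 ± 0.16 in SP cells (SD, n = 3), and Nusap1, a spindle protein, differed by -0.36 (SE 0.26). The integrated stress response list rose (15 of 19 members above 0, mean 0.13, adjusted p = 0.000167), with Asns, asparagine synthetase, at 0.27 (SE 0.24) and Psat1, an enzyme of serine synthesis, at 0.18 (SE 0.18). Endoplasmic reticulum chaperones (16 of 18 above 0, mean 0.07, adjusted p = 0.00853) and Myc targets of ribosome biogenesis (16 of 19, mean 0.08, adjusted p = 0.00912) rose as well. Interferon response genes fell (12 of 14 below 0, mean -0.15, adjusted p = 0.00683), which the paired fit did not call (adjusted p = 0.0582). Each of these 4 lists had an adjusted p = 0.975 with an estimated correlation. No member of any list passed the threshold, whether adjusted over all genes or adjusted over the list alone.

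The mitosis difference rested on replicate 2: the list mean relative to all genes was 0.12, -0.60 and -0.20 in pairs 1, 2 and 3, and the call was lost without the SP array or the pair of replicate 2. The stress response, chaperone and Myc target calls were lost without that array or pair as well. The stress response call was also lost without the non-SP array of replicate 1, the Myc target call without the non-SP array of replicate 3, and the chaperone call without the latter, the SP array of replicate 1 or pair 1. The interferon call was lost without either array of replicate 1, their pair or the SP array of replicate 3. No gene was called by limma in A2C12, with 1 gene at an unadjusted p under 0.05, and the paired fit also called 0, with 187. Both counts lie below a share of 0.05 of the 10916 genes, as do the unpaired counts of the other SP comparisons below. The unpaired SE holds the differences between pairs (median SE 0.28 against 0.11 in the paired fit), so the unpaired counts do not show that few genes differ. In both fits the variance of a gene is pooled over all lines. The SEs and counts given for A2C12 therefore do not reflect the spread of that line alone. The unpaired SE of the transporter gene Abcc1 was 0.40 in both A2C12 and cRAF_cMYC. Its SD among non-SP arrays was 0.13 in A2C12 and 0.91 in cRAF_cMYC. An SE not called paired is from the unpaired fit. The 5 genes with the smallest p were Col12a1, a fibril-associated collagen (-0.58, SE 0.27), Ube2c (-0.37, SE 0.22), the growth factor Igf2 (-0.59, SE 0.38), Hypk (-0.60, SE 0.39) and Gdpd1 (0.41, SE 0.28). The other probe sets of Col12a1 differed by -0.24, 0.04 and 0.07.

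In the line labelled betaD5, the hypoxia list rose in SP cells, with 16 of 20 members above 0 and a mean of 0.26 (log2; camera, adjusted p = 0.000561; adjusted p = 1 with an estimated correlation). Kdm3a, a histone demethylase induced by low oxygen, differed by 0.79 (SE 0.39) and Pfkfb3, which makes the activator of glycolysis fructose 2,6-bisphosphate, by 0.65 (SE 0.34), both higher in SP cells of 3 of 3 pairs. In the paired fit 8 of the 20 members passed adjusted over the list alone and fry called the list (adjusted p = 0.0246). Camera with a correlation estimated in that fit did not call it (adjusted p = 0.31). The dye transporter Abcg2 went from 10.75 ± 0.11 to 11.19 ± 0.32 (SD, n = 3), a difference of 0.44, higher in 3 of 3 pairs (paired 95% interval 0.18 to 0.69). By pair the difference was 0.21, 0.66 and 0.43, and the SP arrays of pairs 2 and 3 had a raised 3'/5' ratio of Gapdh. Abcg2 passed the threshold in the paired fit adjusted over the list alone (adjusted p = 0.0318) and not over all genes (adjusted p = 0.298). In the same fit Btg2, an antiproliferative immediate early gene, at -1.40 (paired SE 0.33), Egr1, an early growth response factor, at -0.49 (paired SE 0.13), and the chaperone Hspa1a at -0.75 (paired SE 0.20) also passed adjusted over their lists alone. The other probe set of Btg2 differed by 0.20.

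No gene was called by limma in betaD5 over all genes, with 14 at an unadjusted p under 0.05. The paired fit called 0, with 1298, and a smallest adjusted p of 0.298. With the mean 3'/5' ratio of Gapdh and Actb on each array as a covariate it called 34, among them Eif4e, a translation initiation factor, at 0.95, and Msantd3 at 1.11, chosen after their values were seen. From non-SP to SP the Gapdh and Actb ratios changed by 0.66 and 0.88 in pair 2, 0.93 and 0.79 in pair 3, and -0.23 and 0.03 in pair 1. The covariate thus follows the pairs, and these calls may lean on pair 1, which resembled cRAF_cMYC arrays. Without the covariate, the 5 with limma's smallest p were Zfp472 (0.86, SE 0.31), the ribosomal protein gene Rpl12 (1.09, SE 0.39), Snhg7 (0.61, SE 0.24), Btg2, and Arrdc3 (0.74, SE 0.31). The 3'/5' ratio of Gapdh was raised in the SP arrays labelled betaD5 2 and 3, at 0.76 and 0.97 (log2) against at most 0.56 in any non-SP array. Without the pairs labelled betaD5 1 and cRAF_cMYC 3 the paired fit called 15 genes in betaD5, 6 higher and 9 lower in SP cells, among them Cenpb (-1.41) and Gadd45b (-0.97), chosen after their values were seen. The betaD5 pairs left there are 2 and 3, so these calls are not free of RNA quality and rest on a pairing that was not settled. The hypoxia list lost its call without the non-SP array of replicate 2 or 3 or the SP array of replicate 1, and without the last its mean was -0.10 relative to all genes. That setting keeps the non-SP array of a pair that resembled cRAF_cMYC arrays, so its value may hold line differences. No pair left out lost the call, and by pair the mean was 0.24, 0.33 and 0.15.

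In the line labelled cRAF_cMYC, 4 lists rose in SP cells. All 19 Myc targets of ribosome biogenesis lay above 0 (mean 0.18, adjusted p = 6.85e-05), with Pno1, a ribosome assembly factor, at 0.34 (SE 0.33) and Wdr12, another one, at 0.25 (SE 0.30). Of 20 hypoxia genes 15 lay above 0 (mean 0.21, adjusted p = 0.000418), with Kdm3a at 0.97 (SE 0.39) and Pfkfb3 at 0.83 (SE 0.34). Of 26 DNA replication genes 24 lay above 0 (mean 0.15, adjusted p = 0.000782), with the helicase subunit Mcm3 at 0.37 (SE 0.36) and the origin licensing factor Cdc6 at 0.35 (SE 0.34). The integrated stress response list had 17 of 19 above 0 (mean 0.15, adjusted p = 0.00452), with Chac1, a glutathione-degrading enzyme, at 0.51 (SE 0.51). All 4 had an adjusted p = 0.983 with a correlation estimated without the pairing. Estimated in the paired fit, camera gave an adjusted p = 0.703 for hypoxia and 0.844 for each of the others. The fibroblast and stromal list, with 1 of 13 members above 0 and a mean of -0.18, was called in the paired fit alone (adjusted p = 0.0039 against 0.0512; adjusted p = 0.844 in the paired fit with an estimated correlation). There Postn, a matrix protein, at -0.57 (paired SE 0.16) and Mfap5, a microfibril protein, at -0.58 (paired SE 0.13) passed adjusted over the list alone.

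In the paired fit 15 list memberships in cRAF_cMYC passed adjusted over the list alone, a gene on several lists counting for each. Of these 5 were of the hypoxia list, and none passed without the pairing. Abcg2 went from 10.69 ± 0.24 to 10.94 ± 0.36 (SD, n = 3), a difference of 0.25 with a paired 95% interval of -0.01 to 0.50. No gene was called by limma in cRAF_cMYC, with 18 at an unadjusted p under 0.05, and the paired fit called 0, with 899. The 5 with the smallest p were Jarid2, a Polycomb cofactor (0.80, SE 0.30), the receptor Scara5 (-0.88, SE 0.34), Msl2 (0.57, SE 0.22), Kdm3a, and the linker histone H1f2 (-0.69, SE 0.28). The other probe set of Scara5 differed by 0.05, and those of H1f2 by -0.46 and 0.07. The Myc target call was lost without the non-SP array of replicate 2, the replication call without the non-SP array of replicate 1 or the SP array of replicate 2, and the hypoxia call without the non-SP array of replicate 3 or the SP array of replicate 1 or 2. Without the non-SP array of replicate 3 the hypoxia mean relative to all genes was -0.05, and without the SP array of replicate 3 it was 0.40. Either setting keeps 1 array of a pair that resembled betaD5 arrays, so these values may hold line differences. No pair left out lost the hypoxia call, and by pair the mean was 0.12, 0.19 and 0.27. The stress response call was lost without the non-SP array of replicate 1 or 2, the SP array of replicate 2 or pair 1.

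Averaged over the 3 lines, SP cells had higher values of Myc targets of ribosome biogenesis (19 of 19 above 0, mean 0.13, adjusted p = 2.42e-05), hypoxia genes (16 of 20, mean 0.16, adjusted p = 4.25e-05) and integrated stress response genes (17 of 19, mean 0.12, adjusted p = 0.00282). They had lower values of mitosis genes (21 of 27 below 0, mean -0.05, adjusted p = 0.00721), interferon response genes (11 of 14, mean -0.11, adjusted p = 0.0122) and fibroblast and stromal markers (11 of 13, mean -0.11, adjusted p = 0.0217). Relative to all genes the mitosis list was nevertheless higher in SP cells of 5 of 9 pairs, the interferon list in 3 and the fibroblast list in 1, and without the pair A2C12 2 the mitosis mean was 0.00. The Myc target, hypoxia and stress response lists were higher in 7, 8 and 7 of 9. Among lists that camera did not call, immediate early genes and Wnt targets were higher in 1 of 9 each. Their unadjusted exact sign-flip p was 0.0156 and 0.0195, against 0.0156 for the hypoxia list. Each of the 6 called lists had an adjusted p = 0.946 with a correlation estimated without the pairing. In the paired fit the estimated correlation was 0.06 for hypoxia, against 0.51 without the pairing, and 0.67 for mitosis, against 0.58. Camera with these paired estimates gave an adjusted p = 0.311 for hypoxia, 0.862 for mitosis and 0.699 for each of the others. Kdm3a differed by 0.56 (SE 0.22), higher in 8 of 9 pairs, and Pfkfb3 by 0.43 (SE 0.20), higher in 7 of 9. Among Myc targets Wdr12 differed by 0.24 (SE 0.17) and Ppan by 0.14 (SE 0.11). Chac1 differed by 0.45 (SE 0.29) and Psat1 by 0.19 (SE 0.11). Within the mitosis list Ube2c differed by -0.26 (SE 0.13), whereas Ccnf, a cyclin of the G2 phase, differed by 0.30 (SE 0.23). The interferon-induced genes Xaf1 and Oas1a differed by -0.28 (SE 0.24) and -0.15 (SE 0.14), and the collagen genes Col6a2 and Col5a1 by -0.12 (SE 0.14) and -0.16 (SE 0.19).

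**Figure D2:**
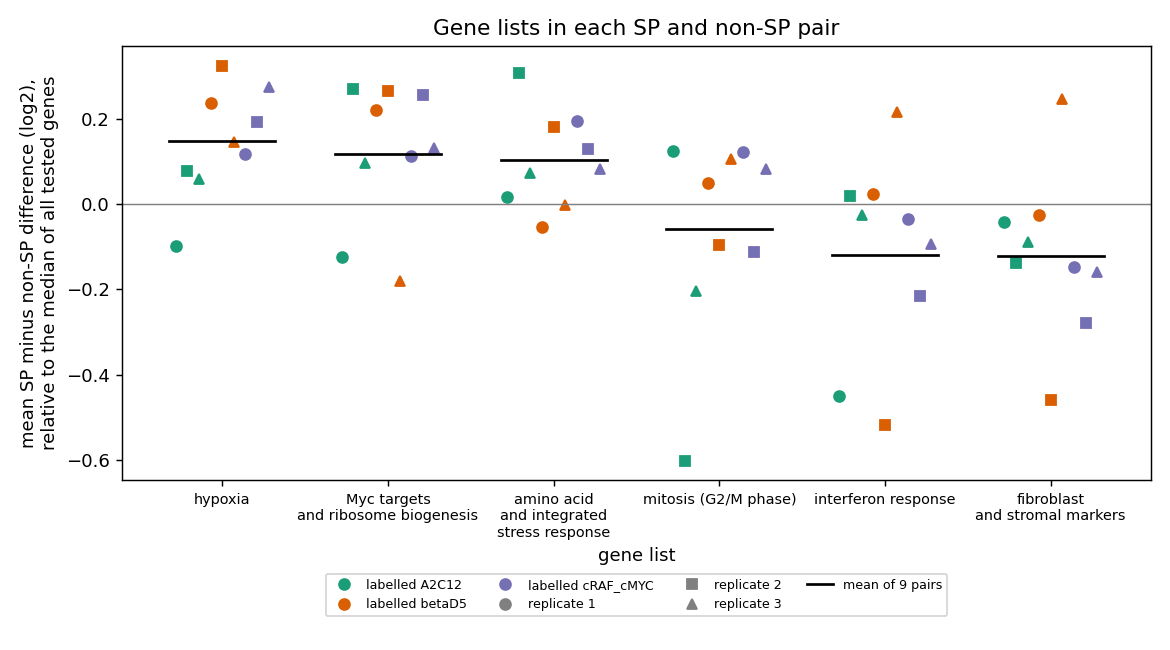
Mean SP minus non-SP difference (log2, vertical axis, relative to the median of all tested genes in the same pair) of the 6 lists called over the 3 lines, 1 point for each of the 9 pairs, coloured by labelled line and shaped by replicate, with black bars for the mean of the pairs. The hypoxia list lies above 0 in 8 of 9 pairs with a mean of 0.15, and the low mitosis mean owes most to the pair A2C12 2 at -0.60.

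Of the dye and drug efflux transporters, 5 of 11 lay above 0 in the average over the lines and the list was not called (adjusted p = 0.905). Abcg2 differed by 0.25 (SE 0.13), higher in SP cells of 8 of 9 pairs. Its paired 95% interval was 0.10 to 0.39, and it passed the threshold in the paired fit adjusted over the list alone (adjusted p = 0.0361) but not over all genes (adjusted p = 0.22). The P-glycoprotein genes Abcb1b and Abcb1a differed by 0.22 (SE 0.18, 6 of 9 pairs) and 0.13 (SE 0.19, 5 of 9 pairs). Abcc1 differed by -0.01 (SE 0.23) and Myc by 0.02 (SE 0.17). The other probe sets of Abcb1b, Abcb1a and Abcc1 differed by -0.12, 0.29 and 0.28. In A2C12 Abcg2 was 8.54 ± 0.04 in non-SP and 8.60 ± 0.26 in SP cells (SD, n = 3), with a paired 95% interval of the difference of -0.19 to 0.31. The variance behind this interval is pooled over the lines.

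**Figure D3:**
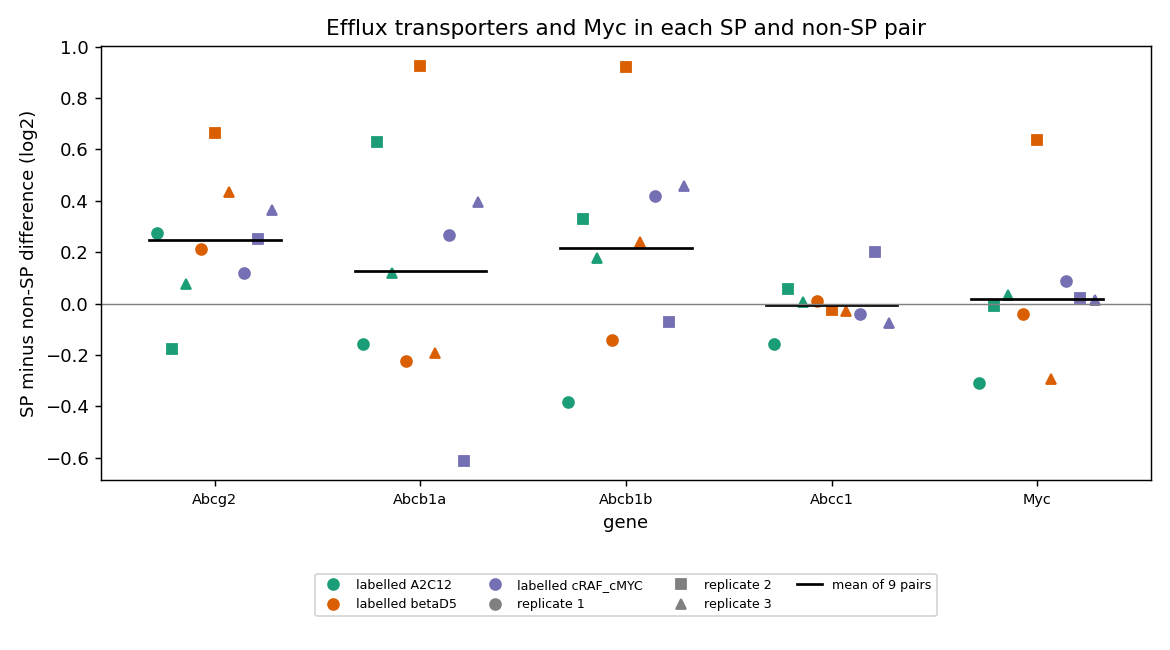
SP minus non-SP difference (log2, vertical axis) of 4 efflux transporter genes and Myc in each of the 9 pairs, coloured by labelled line and shaped by replicate, with black bars for the mean of the pairs. Abcg2 lies above 0 in 8 of 9 pairs with a mean of 0.25, and Abcc1 and Myc have means of -0.01 and 0.02.

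The paired fit passed 25 list memberships adjusted over the list alone in the average, against 0 without the pairing, a gene on several lists counting for each. Of all 10916 genes 1437 lay at an unadjusted p under 0.05 in that fit. The memberships included 10 of the 20 hypoxia genes, among them Kdm3a, Ddit4 (0.25), Pfkfb3 and Ero1a (0.29). The heat shock genes Hspa1a and Hspa1b differed by -0.62 (paired SE 0.12) and -0.29 (paired SE 0.07), lower in SP cells of 9 and 8 of 9 pairs. The immediate early genes Egr1 and Btg2 differed by -0.36 (paired SE 0.07) and -0.78 (paired SE 0.19), each lower in 8 of 9 pairs, and the Wnt targets Ccn4 and Ccn5 by 0.16 (paired SE 0.05) and -0.20 (paired SE 0.06). The other probe set of Btg2 differed by 0.03 in the average, so its decrease rests on 1 probe set. The alveolar type II list, a set of surfactant cell markers, was not called (adjusted p = 0.327), with Etv5, a transcription factor, at 0.23 (SE 0.22). Nor were stem and progenitor markers (8 of 9 above 0, adjusted p = 0.343), with the hyaluronan receptor Cd44 at 0.21 (SE 0.18) and the integrin Itga6 at 0.34 (SE 0.36). Leukocyte markers (adjusted p = 0.579), endothelial markers (adjusted p = 0.404) and epithelial junction genes (adjusted p = 0.343) were not called either. Of the club and ciliated cell markers 3 of 9 and 1 of 9 lay above the filter, and these lists were not tested.

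No gene was called by limma in the average over the lines, with 36 at an unadjusted p under 0.05, and the paired fit called 0, with 1437 and a smallest adjusted p of 0.151. The 5 with the smallest p were Mid1, a microtubule-associated ubiquitin ligase (0.57, SE 0.20), Mir22hg (-0.36, SE 0.14), the zinc finger gene Zfp157 (0.39, SE 0.15, higher in 9 of 9 pairs), Cpeb2 (0.43, SE 0.17) and Epc1 (0.41, SE 0.16). The other probe sets of Mid1 differed by 0.01 and -0.07, and those of Epc1 by -0.23 and -0.10. The 3'/5' ratio of Gapdh was raised in the SP arrays of the pairs labelled betaD5 2 and 3, which are among the 8 pairs with a higher hypoxia mean. With that ratio as a covariate the paired fit called 3 genes in the average, Msantd3 (0.54), Eif4e (0.40) and Grpel2 (0.50), and without both pairs it called Nfix (-0.65), all chosen after their values were seen. The hypoxia call was lost without the SP array labelled betaD5 1 and the Myc target call without the non-SP array of that pair. With a whole pair left out neither call was lost. The stress response call was lost without the SP array labelled betaD5 1 or the SP array A2C12 2. The mitosis, interferon and fibroblast calls were lost with 6, 6 and 8 of the 18 arrays left out in turn. The test, mean and median of a list differed in sign for the uncalled heat shock list, which had a mean of -0.01, a median of 0.09 and a test direction of up. The mean and median of the uncalled Nrf2 target and mesenchymal lists were above 0 while camera ranked them below the other genes, and the alveolar type I and ribosomal protein lists, with means of -0.01 and 0.00, also differed in sign. Within single lines the mean, median and test differed in sign for other lists, among them p53 targets in A2C12, mitosis genes in betaD5 and the efflux transporters in betaD5 and cRAF_cMYC, none of them called there.

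The SP differences of the mitosis genes were higher in betaD5 than in A2C12 (26 of 27 members, mean 0.28, adjusted p = 1.26e-07) and in cRAF_cMYC than in A2C12 (27 of 27, mean 0.27, adjusted p = 1.99e-09). Those of the hypoxia genes were higher in betaD5 (17 of 20, mean 0.25, adjusted p = 0.00762) and in cRAF_cMYC (14 of 20, mean 0.20, adjusted p = 0.0193) than in A2C12. Relative to all genes the hypoxia mean turned to -0.10 in betaD5 without its SP array 1. In cRAF_cMYC it turned to -0.05 without the non-SP array 3. Each of these settings keeps 1 array of a pair that resembled the other line. DNA replication genes had higher SP differences in cRAF_cMYC than in A2C12 (25 of 26, mean 0.20, adjusted p = 0.000277) and endoplasmic reticulum chaperones had lower ones (15 of 18, mean -0.10, adjusted p = 0.0193). The 4 aryl hydrocarbon receptor targets had higher SP differences in betaD5 than in A2C12 (mean 0.55, adjusted p = 0.0188), a call that the paired fit did not make (adjusted p = 0.377). Relative to all genes their mean was 0.41, 1.47 and -0.80 in the pairs betaD5 1, 2 and 3, and the SP arrays of pairs 2 and 3 have the raised 3'/5' ratio. With an estimated correlation the smallest adjusted p was 0.999 for betaD5 and 0.985 for cRAF_cMYC against A2C12. No list differed between cRAF_cMYC and betaD5. Each of these labels holds a pair that resembled the other line, so this contrast, and its part in the F test, may miss a difference. No single gene differed in its SP effect between lines by limma's F test, with 1 at an unadjusted p under 0.05, and the paired fit gave 0, with 381.

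The SP differences of betaD5 and cRAF_cMYC correlated across the 10916 genes (Pearson r = 0.514, Spearman rho = 0.479), with 66.3% of genes of the same sign. Those of A2C12 correlated at 0.128 (rho = 0.1245) with betaD5 and at 0.0163 (rho = 0.0018) with cRAF_cMYC. With 1 array left out, these r ran from 0.1566 to 0.5164, from -0.0606 to 0.1749 and from -0.1414 to 0.1217. Genes are not independent replicates, so no p is attached. Without the pairs labelled betaD5 1 and cRAF_cMYC 3 the correlation of betaD5 and cRAF_cMYC was 0.1225. Over all pairs, the r between single pairs of a line was -0.39 to 0.35 for A2C12, -0.23 to 0.09 for betaD5 and 0.19 to 0.40 for cRAF_cMYC, and between single pairs of betaD5 and cRAF_cMYC it was -0.22 to 0.55.

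Among non-SP cells, Aldh3a1, an aldehyde dehydrogenase, was highest in A2C12 at 11.97 ± 0.34 against 5.46 ± 1.17 in betaD5 and 4.72 ± 0.94 in cRAF_cMYC (SD, n = 3). Aldh1a1, a retinaldehyde dehydrogenase, was 4.85 ± 0.96 in A2C12, 14.00 ± 0.10 in betaD5 and 13.19 ± 0.77 in cRAF_cMYC. The receptor Scara5 and the prostaglandin receptor Ptger3 stood 5.41 (SE 0.29) and 4.87 (SE 0.60) above the mean of the other lines in A2C12. The 3 genes farthest above the other lines were Gpm6a (5.22, SE 0.57), Aldh1a1 (4.98, SE 0.46) and Ivns1abp (4.65, SE 0.23) in betaD5, and Upk3b (4.29, SE 0.43), Ivns1abp (4.27, SE 0.23) and Ndn (4.16, SE 0.27) in cRAF_cMYC. These 5 genes were high in both lines and low in A2C12, at 3.03 to 4.85 against a lowest value of 2.28 on any array, so the size and order of these differences are uncertain. The sizes for Aldh3a1 and Ptger3 are uncertain too, since both were low in betaD5 and cRAF_cMYC, at 4.61 to 5.64. Scara5 stood higher there, at 7.67 and 8.32.

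The values of all genes as deposited were shifted between the lines, with a median difference from A2C12 of 0.71 (log2) in betaD5 and 0.45 in cRAF_cMYC. Counts as deposited include those shifts, and single list genes are given relative to them or after quantile normalization. Limma called 4842 genes over the 3 lines. It called 6021 between betaD5 and A2C12, 5791 of them higher in betaD5, and 3115 between cRAF_cMYC and A2C12, 2866 of them higher in cRAF_cMYC. With 1 array left out these 3 counts ran from 2866 to 5761, from 4517 to 6482 and from 1562 to 4986. After quantile normalization the calls between betaD5 and A2C12 were 1701 higher and 1443 lower, and those between cRAF_cMYC and A2C12 were 1314 higher and 1126 lower. After centring on array medians they were 1419 higher and 1176 lower, and 1293 higher and 786 lower.

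Hedgehog components were higher than in A2C12 under both scalings for 3 of 6 tested members in each line. Relative to the median shift, Gli3 stood 2.98 above A2C12 in betaD5 and 3.07 in cRAF_cMYC, and after quantile normalization 3.04 and 3.11. The transcription factor Gli2 stood 2.48 and 3.17 and the transducer Smo 1.17 and 1.15 above A2C12 after quantile normalization. Of 13 fibroblast and stromal markers 7 were higher in betaD5 and 9 in cRAF_cMYC, and after quantile normalization 4 and 6, among them Col1a2 (1.36 and 1.52) and Dcn (2.61 and 3.29). Of 26 DNA replication genes 24 were higher in betaD5 and 12 in cRAF_cMYC, and 9 and 7 after quantile normalization, among them Hells (1.72 and 1.41) and Cdt1 (1.05 and 0.89). Of 27 mitosis genes 19 and 9 were higher, and 4 and 4 after quantile normalization, with 1 lower in betaD5. Of 10 glycolysis genes none was called as deposited, and 8 were lower in each line after quantile normalization, among them Pfkp (-1.33 and -1.32) and Pgam1 (-0.61 and -0.62). Abcg2 stood 1.53 and 1.71 above A2C12 after quantile normalization, and the p53 target Pmaip1 6.80 and 6.99. Egr2 (-3.64 and -3.14), the Notch target Nrarp (-2.92 and -2.52) and Ccn5 (-3.78 and -3.63) were lower than in A2C12. Adjusted over the list alone, 4 Hedgehog, 7 fibroblast, 24 replication and 20 mitosis genes were higher in betaD5 as deposited, and 3, 10, 16 and 9 in cRAF_cMYC.

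Between cRAF_cMYC and betaD5, limma called 0 genes among non-SP cells, with 689 at an unadjusted p under 0.05 and a smallest adjusted p of 0.592. Without the pairs labelled betaD5 1 and cRAF_cMYC 3 it called 1222.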

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

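The tests of exchanged labels, of normalization, of a mixture, of RNA length and of the hypoxia list, and the 9 other ways to part the betaD5 and cRAF_cMYC pairs, were chosen only after the result was seen, and the bioB test and the remaining splits of the samples were not.

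The pairs labelled betaD5 1 and cRAF_cMYC 3 stood apart from the other arrays of their label. An axis of the 44 genes that lay 16-fold apart between the pairs betaD5 2 and 3, at position 0, and cRAF_cMYC 1 and 2, at position 1, put betaD5 1 at a median of 1.037 and cRAF_cMYC 3 at -0.042, where an exchange of both labels would put them. Normalization or an array batch as the whole cause is argued against by the 44 genes that were 16-fold apart between betaD5 1 and betaD5 2 or 3 after quantile normalization, against 0 between A2C12 pairs. A mixed culture is argued against by the median linear share of the cRAF_cMYC level, 1.133 in betaD5 1 and -0.003 in cRAF_cMYC 3. An exchange of labels remains a candidate explanation, different sublines under 1 name were not tested, and which name belongs to which set of arrays is not settled by these values.

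The 3'/5' log2 ratio of Gapdh, a control outside the comparisons, was 0.7591 in the SP array labelled betaD5 2 and 0.9743 in betaD5 3, above the 0.5587 of the highest non-SP array. Of the 8 SP minus non-SP differences of Gapdh, Actb, Tfrc and Pcx ratios in these pairs, 7 exceeded the largest of the other 7 pairs, as shorter cDNA or degraded RNA would give. Hybridization of these arrays is argued against, since 0 of 2 differences of the spiked bioB ratio did so. No biological explanation was tested.

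The hypoxia list was higher in SP cells in 8 of 9 pairs, with a mean of 0.15 relative to all genes. Without the pairs labelled betaD5 2 and 3 its mean over the 7 other pairs was 0.123 (SD 0.127, higher in 6 of 7). The exact sign-flip p = 0.0625 bears on chance in 7 pairs and does not settle the part of RNA quality. In A2C12 1 to 3, betaD5 1 and cRAF_cMYC 1 to 3 the Gapdh ratio changed by 0.13, -0.04, 0.03, -0.23, 0.06, -0.56 and -0.07. The hypoxia mean there was -0.10, 0.08, 0.06, 0.24, 0.12, 0.19 and 0.27. A raised Gapdh ratio in SP cells thus does not account for the rise in betaD5 1 and cRAF_cMYC 2 and 3. Over all 9 pairs the exact sign-flip p was 0.0156, and 0.1875 adjusted over the lists, so chance is not excluded. A response of SP cells to low oxygen, or to the sort, was not tested.

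Lists whose SP difference differed between lines were the aryl hydrocarbon receptor targets, by 0.5511 in betaD5 against A2C12, the mitosis genes, by 0.2752, and the hypoxia genes, by 0.2519. For cRAF_cMYC against A2C12 they were DNA replication, by 0.2003, mitosis, by 0.2746, hypoxia, by 0.1979, and endoplasmic reticulum chaperones, by -0.1013. The receptor targets lay at 0.41, 1.47 and -0.80 in the pairs betaD5 1, 2 and 3, the last 2 with the raised 3'/5' ratio. None of these calls held with an estimated correlation, and the mitosis and DNA replication differences rest in part on the pair A2C12 2. Mitosis lay there at -0.60 against 0.12 and -0.20 in the other A2C12 pairs, and replication at -0.25 against 0.07 and 0.04. The hypoxia mean changed sign in betaD5 without its SP array 1 and in cRAF_cMYC without its non-SP array 3. Each leaves 1 array of a pair that resembled the other line, so these values may hold line differences. By pair the hypoxia mean was 0.24, 0.33 and 0.15 in betaD5 and 0.12, 0.19 and 0.27 in cRAF_cMYC. No pair left out lost the hypoxia call within betaD5 or cRAF_cMYC.

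The 6 arrays of a line split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. Any split reaches a count of 0 genes, so the gene counts of SP against non-SP cells are given as values and test nothing. In A2C12, 10 of 10 splits gave at least the 0 genes of the real split (highest other 0) and 9 of 10 at least its 5 lists (highest other 11). In betaD5 these were 10 of 10 for 0 genes (highest other 0) and 8 of 10 for 1 list (highest other 9). In cRAF_cMYC they were 10 of 10 for 0 genes (highest other 2656) and 3 of 10 for 4 lists (highest other 8). The split that called 2656 genes points to a structure of the samples. With the arrays split within each line, 100 of 100 splits gave at least the 0 genes of the average (highest other 573, again pointing to such a structure). With SP and non-SP exchanged within pairs, 59 of 100 gave at least its 6 lists (highest other 12), so chance is not excluded for these lists. With the 9 pairs parted into 3 sets of 3, 100 of 100 gave at least the 0 genes of the difference in SP effect (highest other 0). By the same partitions 2 of 100, the labelled one included, gave at least the 4842 genes that differed between the lines. The other of these kept the A2C12 pairs together, put betaD5 1, betaD5 3 and cRAF_cMYC 2 in 1 set, and called 5307. Another partition that kept the A2C12 pairs together called 3951. The share holds for ways to part these 9 pairs, whose replicates may be technical, so it does not exclude chance between separate cultures. Of all 9 other ways to part the betaD5 and cRAF_cMYC pairs, 5 called more than 4842 genes (4895, 4991, 5307, 5475 and 7079), so the count says nothing for the labels betaD5 and cRAF_cMYC.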

How the results depend on the processing

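The settings chosen only after the data had been seen were those that combine the replicate block with another change, those that leave out pairs, and the sign-flip test. Of 2164 values of named genes under alternatives, 2162 stayed on their side of the threshold, 84 of them uncalled with a change of sign, and 2 passed it. Of 4864 list values 4600 stayed on their side, 492 of them uncalled with a change of sign, while 112 lost a call, 142 gained one and 10 changed the direction of the test, called before or after. Of 483 counts 68 moved by over 1.5 times. Causes were not tested except where stated. The number of arrays limits the precision.

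With quantile normalization 2637 genes differed between lines among non-SP cells and 3144 between betaD5 and A2C12, and 3 lists were called in betaD5. With median centring these gene counts were 2170 and 2595. With no filter they were 8231 and 10568, with 2 lists in A2C12, 4 in betaD5 and an r of A2C12 and betaD5 of -0.0113, and with every probe set 11427 and 14813, with 5956 for cRAF_cMYC against A2C12, since more features were tested. Array weights gave 8206 between the lines and 6328 for cRAF_cMYC against A2C12. Camera with an estimated correlation and fry called 0 lists in A2C12, betaD5, cRAF_cMYC and the average, as did the replicate block with an estimated correlation. The block with fry called 0 in A2C12 and cRAF_cMYC and 1 in the average, and the exact sign-flip test called 0. The sign-flip test has too few sign patterns for a list standing alone to pass adjusted over the lists, so its count says little.

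Without the pairs labelled betaD5 1 and cRAF_cMYC 3, 1222 genes differed between cRAF_cMYC and betaD5, 7 lists were called in cRAF_cMYC, the r of betaD5 and cRAF_cMYC was 0.1225, and the replicate block called 15 genes in betaD5. Without the pairs labelled betaD5 2 and 3 the block called 2 genes in betaD5 (Cdc37 at 0.98 and Nfix at -1.40), 2 in cRAF_cMYC (H1f2 at -0.6876, adjusted p = 0.0494, and Il33 at -0.92) and 1 in the average (Nfix at -0.65), named after their values were seen, with 5 lists in betaD5 and 3 in the average. The Nrf2 target list in betaD5 was then called at 0.275, the opposite direction. The lone betaD5 pair is there assumed to vary like the others. The block with quantile normalization called 3 lists in A2C12, and with no filter 2 in A2C12, 5 in betaD5 and 7 in cRAF_cMYC. With the mean 3'/5' ratio of Gapdh and Actb as a covariate the block called 34 genes in betaD5, among them Wdfy1 at 0.707 (adjusted p = 0.0439), 3 in the average (Msantd3 at 0.54, Eif4e at 0.40 and Grpel2 at 0.50) and 3 lists in betaD5.

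With 1 array or pair left out, 0 genes were called for SP in each line, the average and the difference between lines. With 1 array left out, 0 were called between cRAF_cMYC and betaD5. The differences between lines among non-SP cells and the r were not computed with 1 pair left out. The genes differing between lines ran from 2866 (without the non-SP array A2C12 3) to 5761 (without cRAF_cMYC 1), those of betaD5 against A2C12 from 4517 to 6482, and those of cRAF_cMYC against A2C12 from 1562 (without cRAF_cMYC 2) to 4986 (without cRAF_cMYC 1). With 1 array or pair left out, the lists called ran from 2 to 7 in A2C12, 1 to 8 in betaD5, 2 to 8 in cRAF_cMYC and 3 to 11 in the average. The r ran from -0.0606 to 0.1749 for A2C12 and betaD5, from -0.1414 to 0.1217 for A2C12 and cRAF_cMYC, and from 0.1566 (without the non-SP array cRAF_cMYC 3) to 0.5164 for betaD5 and cRAF_cMYC. Lists whose test changed direction, called before or after, with their means relative to all genes, were cholesterol synthesis in betaD5 (0.2444 without the non-SP array 1 and 0.1441 without the SP array 2, down to -0.2869 without the SP array 1), hypoxia in betaD5 (-0.1049 without the SP array 1, up to 0.5592 without the non-SP array 1), the stress response in A2C12 (-0.0142 without the SP array 2, up to 0.2526 without the SP array 1), Myc targets in A2C12 (-0.0115 without the non-SP array 3, -0.0633 without the SP array 2, -0.0045 without pair 2, up to 0.1893 without pair 1) and inflammatory genes in A2C12 (0.1722 without the SP array 1, 0.3757 without pair 1, down to -0.5098 without the SP array 2). The mean of other called lists changed sign while the test lost its call without changing direction. These were hypoxia in cRAF_cMYC (-0.052 without the non-SP array 3, up to 0.4033 without the SP array 3), the fibroblast list in the average (up to 0.0374 without the SP array cRAF_cMYC 3), interferon genes in A2C12 (0.0034 without pair 1) and mitosis in the average (0.0024 without pair A2C12 2).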

Other observations

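The values of single genes in this part, and the regrouping of the pairs, were chosen only after the result was seen.

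Several genes differed widely between arrays that carry the same label betaD5 or cRAF_cMYC. Efemp1, an extracellular matrix gene, was 13.87 in the non-SP array betaD5 1 and 4.37 in betaD5 2, and 13.90 in cRAF_cMYC 2 and 3.93 in cRAF_cMYC 3. The growth factor homologue Fgf13 went the other way, at 6.18 in betaD5 1, 12.30 in betaD5 2, 4.47 in cRAF_cMYC 2 and 12.35 in cRAF_cMYC 3. Xist, the RNA of the inactive X chromosome, was 12.53 in betaD5 1 and 5.77 in betaD5 2, and 11.33 in cRAF_cMYC 2 and 5.89 in cRAF_cMYC 3, while the A2C12 arrays lay between 12.03 and 12.27. Eif2s3y, a gene of the Y chromosome, was 6.20 in betaD5 1, 6.47 in cRAF_cMYC 2, 3.98 in betaD5 2 and 3.58 in cRAF_cMYC 3, and at most 3.04 in A2C12. Its values in betaD5 1 and cRAF_cMYC 2 lay below the medians of these non-SP arrays, 6.51 and 6.53.

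With the 6 pairs parted into betaD5 1 with cRAF_cMYC 1 and 2, and betaD5 2 and 3 with cRAF_cMYC 3, 1629 genes differed between both sets among non-SP cells and 7079 over the sets and A2C12, against 0 and 4842 as labelled. The paired fit then called 3 genes between SP and non-SP cells in the first set, 606 in the second and 37 in the average, against 0 in each as labelled. The 8 remaining ways of parting the pairs into 2 sets of 3 gave 0 genes between the sets, and the paired fit called up to 70 genes in a set and up to 4 in the average. The second set holds the SP arrays with the raised 3'/5' ratio of Gapdh, so its SP count is not free of RNA quality.

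Tiparp, an aryl hydrocarbon receptor target, differed between SP and non-SP cells by 0.94 (SE 0.45) in betaD5 and 0.97 (SE 0.45) in cRAF_cMYC, and by 0.61 (SE 0.26) in the average, higher in 7 of 9 pairs, and was not called.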
